A study of Mus musculus with 12 samples.

How the data were processed

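Small RNA was sequenced from extracellular vesicles (EVs, membrane particles released by cells) of adipose tissue and from the hippocampus of male C57BL/6J mice that ate chow or a high-fat diet (HFD) for 12 weeks, per the labels and the series' design text. The 12 libraries fall into 4 groups of 3, namely chow EVs, HFD EVs, chow hippocampus and HFD hippocampus. RNA was taken up in Trizol, per the labels, and Novogene built and sequenced the small RNA libraries, per the series' design text. The labels number the libraries of a group but do not say that they came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

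The deposited values are read counts per mature miRNA, 1 column per library, per the file headers, and no normalisation had been applied to them. Whole numbers with column totals that differed between libraries fitted that description. Bowtie is named in the submitters' processing notes, without a version or a role. The genome build, the miRNA annotation, the counting tool and any filter on reads are not given in the sources used here. Reads that match several miRNAs could therefore have been counted under each of them. Such sharing was looked for in the counts. Pairs of miRNAs whose counts lay within 5% of each other in every library, at a mean of at least 5 CPM, numbered 14 in EVs and 19 in hippocampus. Leaving out 1 member of each removed 13 and 18 miRNAs, which held 1.39% and 22.9% of all counts, the latter mostly because miR-9b-3p repeated the reads of miR-9-5p.

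The EV table held 1084 entries, of which 1038 were known miRNAs and 46 were predicted small RNAs. The hippocampus table held 1163, and 5 of these were blank for the HFD libraries and were left out (they held at most 3 counts in total in the other libraries). Both tables shared 852. The hippocampus table's chow libraries were taken to be its 3 columns headed LFD. The labels do not use that heading, and the assignment is an inference from the numbering and from chow being the only other diet. In addition, 1 column of per-sample values, a 4th headed HFD in the hippocampus table, matched no sample and was not used. It bears on the HFD hippocampus group of 3, where leaving out HFD library 1 or 3 took 65 calls to 8 or 9. Replicates were compared by a chi-square test of the counts of miRNAs with at least 10 in the pair, whose value per degree of freedom lay between 80.4 and 704 for all 12 pairs, so no pair was a repeated library.

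Counts were analysed with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, libraries were scaled with TMM, and the quasi-likelihood F test (glmQLFit with robust fitting, glmQLFTest) was run two-sided with Benjamini-Hochberg adjustment over all miRNAs tested. A miRNA is said to have risen, fallen or been called at an adjusted p under 0.05. Each diet comparison used the 6 libraries of its sample type. The difference of the diet effects between EVs and hippocampus, and the contrast of EVs with hippocampus in chow mice, came from a fit of all 12 libraries over the shared miRNAs. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Within a library the floor of 3 counts corresponds to 0.505 to 1.64 CPM in EVs and 0.233 to 1.29 CPM in hippocampus. Where a group held 0 counts, a bound was computed with 3 counts over the group, and with 1 to 3 counts a ratio of pooled counts is given with an exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

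The lists, the tests of the comparisons, most of the alternative settings and the rule for named miRNAs were fixed before the data were examined, whereas 3 settings and 6 tests of explanations (brain RNA, scaling, blood, a factor shared by all miRNAs, and both tests of miRNAs present with 1 diet alone) were chosen after. The 23 lists were adipogenesis, anti-adipogenic, obesity and inflammation, immune cell, red cell, endothelial, liver, muscle, smooth muscle and fibroblast, epithelial, testis X cluster, neuron, neuronal activity, glia, choroid and ependyma, the Dlk1-Dio3 cluster, let-7, miR-17-92, miR-30, miR-29, miR-34 and miR-449, miR-181 and insulin resistance. Lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The same lists were also tested with an estimated correlation and with fry, whose p asks whether the members move, on balance, to one side. Named miRNAs were the 10 with the largest rise and the 10 with the largest fall per diet comparison among called miRNAs with at least 10 CPM in a group and no overlap between diets, both arms of miR-9, up to 4 abundant members per list, the 10 most abundant miRNAs, the 10 smallest p of the difference between sample types, the 10 largest differences each way between sample types (at least 100 CPM), and miRNAs called in both diet comparisons. Called members of a list that are named as its examples outside this rule were chosen after their values were seen. miR-9-3p is the miRNA this study is known to have followed up, chosen on these samples, so its result here is not independent evidence. The prefix mmu- of the miRNA names is left out of the text.

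Marker shares were sums of the counts of a list over the library total, compared with an exact two-sided permutation test whose smallest p with 3 against 3 is 0.1. Correlations of fold changes used 100000 permutations. Ratios of the 5p to the 3p arm of a hairpin were compared with limma (trend, robust) on log2 ratios with 0.5 counts added. Hairpin positions were taken from the GENCODE annotation of GRCm38 by matching gene symbols, which succeeded for 34 of 40 named miRNAs. Mature sequences were not matched, and the authors' build is not given in the sources used here. A hairpin is placed in an exon or UTR where it overlapped that of any annotated transcript of the gene, though it may be intronic in others.

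The steps were tested on simulated counts with known changes, drawn with the mean proportions, library sizes and dispersions of the real libraries. In the EV diet comparison, 12.5% of tested 2-fold and 67.4% of tested 4-fold changes were recovered, with 2 false calls among 37. In the hippocampus diet comparison the shares were 37.5% and 86.5%, with 1 false call among 64. For the difference between sample types they were 3.57% and 18.3%, with 2 false calls among 15, and for EVs against hippocampus 14.8% and 88.7%, with 1 among 65. In this last simulation both sample types were drawn from 1 shared profile before the changes were made. In the real libraries 412 of 519 miRNAs were called between them, so its false calls do not carry over to that contrast. The let-7 list, with its members doubled, was called in all 20 draws of either diet comparison. The simulated miRNAs were drawn without correlation between them, so these draws do not test list calls where miRNAs vary together. Of 20 hairpins with a 4-fold arm change, 5.15 were recovered on average in EVs and 15.6 in hippocampus.

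The alternatives were other scalings (median-of-ratios size factors, upper quartile, library totals), no filter on low counts or a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, robust fitting switched off, known miRNAs alone, 1 fit of all 12 libraries for the diet comparisons, each library left out in turn, and the replicate number as a block. Keeping miRNAs with the same reads once, thinning libraries to the lowest total and leaving out miR-148a-3p were chosen after seeing the data.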

Results

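Read counts of miRNAs were available for 12 libraries of mice fed chow or a high-fat diet (HFD) for 12 weeks, 3 of adipose tissue EVs and 3 of hippocampus per diet. Totals in the chow EV libraries were 2294878, 2225806 and 2120171 counts, and in the HFD EV libraries 5941955, 1825488 and 1969840 counts. Chow hippocampus libraries held 4094592, 5723921 and 2331091 counts. HFD hippocampus libraries were deeper, at 12874600, 11143775 and 12384458 counts, so depth and diet went together in that tissue. The chow hippocampus libraries are those headed LFD in the deposited counts, an assignment that is an inference.

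In EVs, miR-148a-3p was the most abundant miRNA, at 43.7 ± 12.0% of counts in chow and 23.8 ± 2.71% in HFD libraries (SD, n = 3), and between 21.0% and 57.2% of a single library. It was followed by miR-10b-5p, miR-21a-5p, miR-10a-5p, miR-99a-5p, let-7f-5p, miR-30a-5p, miR-30d-5p, miR-26a-5p and let-7g-5p. In hippocampus, miR-9-5p, a miRNA of the neural lineage, took 23.5 ± 4.46% of counts in chow and 21.3 ± 0.43% in HFD libraries. The rest of the most abundant were miR-9b-3p, which holds the same reads, miR-218-5p, miR-26a-5p, miR-128-3p, miR-127-3p, miR-99a-5p, miR-30a-5p, let-7f-5p and miR-143-3p.

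Which miRNAs of adipose tissue EVs differed with diet was tested between 3 HFD and 3 chow libraries. miR-9-3p, an arm of a hairpin best known from the nervous system, rose most, from 67.3 ± 31.8 CPM in chow to 705 ± 100.1 CPM in HFD EVs, a log2 fold change of 3.39 (SE 0.42, adjusted p = 0.0196). The myeloid miRNA miR-223-3p rose from 19.6 ± 14.1 to 168 ± 23.1 CPM (log2 fold change 3.12, SE 0.55, adjusted p = 0.0226), and its other arm miR-223-5p by 1.40 (SE 0.31, adjusted p = 0.0483). miR-342-3p, abundant in leukocytes, rose from 107 ± 66.1 to 620.0 ± 16.1 CPM (log2 fold change 2.53, SE 0.46, adjusted p = 0.0233). miR-143-3p, which is abundant in smooth muscle and rises in fat cell differentiation, fell from 9815 ± 1519 to 2510.2 ± 930.4 CPM (log2 fold change -1.97, SE 0.32, adjusted p = 0.0217). The endothelial miR-126a-3p fell from 2434 ± 82.0 to 939 ± 26.9 CPM (log2 fold change -1.37, SE 0.23, adjusted p = 0.0217).

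Other miRNAs that rose were miR-9b-5p (log2 fold change 2.45), miR-27b-5p (2.36), miR-142a-5p (1.94), miR-98-5p (1.88), miR-30b-3p (1.84) and miR-335-5p (1.76), the last encoded in an intron of the imprinted gene Mest. Among abundant miRNAs, miR-21a-5p went from 3.74 ± 0.32% to 12.0 ± 0.75% of counts and let-7f-5p from 2.53 ± 0.76% to 7.73 ± 0.42% of counts. Their log2 fold changes were 1.34 (SE 0.22) and 1.31 (SE 0.22), both with an adjusted p of 0.0217. The remaining falls were miR-30a-3p (log2 fold change -2.02) and miR-193a-3p (-1.74). miR-148a-3p had a log2 fold change of -1.28 (SE 0.35) that did not pass, with an adjusted p of 0.0772. It passed without a filter (-1.05, adjusted p = 0.00523) and with DESeq2 (-1.23, adjusted p = 0.0340). The hairpin of miR-223 lies at chromosome X, 96242817 to 96242926, in an exon of the transcript F630028O10Rik. That of miR-342 lies in an intron of Evl on chromosome 12, 108658620 to 108658718, and that of miR-335 on chromosome 6, 30741299 to 30741396. The hairpin of miR-21a lies at chromosome 11, 86584067 to 86584158, in a UTR of Vmp1. That of miR-126a lies at chromosome 2, 26591357 to 26591429, within Egfl7, where it overlaps an exon of an annotated transcript and may be intronic in others. That of miR-143 lies at chromosome 18, 61649196 to 61649258, between genes (GRCm38).

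Camera called 6 of 23 lists with the 6 EV libraries grouped by diet. Groupings of 3 and 3 that mixed the diets gave 0, 2, 4, 4, 2, 5, 4, 3 and 4. Such calls are therefore weak evidence of a diet effect on a list. Of the fixed groups, the obesity and inflammation list rose in HFD EVs by this test at the preset correlation. Of its 13 tested members 5 rose and 0 fell over all miRNAs tested, 10 rose adjusted over the list alone, and the median log2 fold change was 1.28 (camera adjusted p = 9.07e-06; adjusted p = 0.399 with an estimated correlation). Its members include miR-21a-5p, miR-146a-5p, a feedback inhibitor of NF-kB signalling that rose from 5047 ± 527 to 12239 ± 2787 CPM (log2 fold change 1.28, adjusted p = 0.0364), and miR-146b-5p at a log2 fold change of 0.93 (adjusted p = 0.124, but 0.0295 with totals and 0.0146 without a filter). The immune cell list rose as well, with 5 of 11 tested members higher and 0 lower, 8 higher and 1 lower adjusted over the list alone, and a median of 1.40 (camera adjusted p = 6.28e-04; adjusted p = 0.399 with an estimated correlation). It holds miR-223-3p, miR-342-3p, miR-142a-5p and, at a log2 fold change of 0.17 (adjusted p = 0.924), miR-155-5p, and shares 5 tested members with the former list. The value of miR-155-5p was below 0 without chow EV library 1 or 2 or HFD EV library 2, to -0.40 at the lowest. The let-7 family rose, with let-7f-5p and miR-98-5p called among 9 tested members, 6 higher adjusted over the list alone, and a median of 0.86 (camera adjusted p = 0.0106; adjusted p = 0.586 with an estimated correlation). let-7g-5p and let-7i-5p had log2 fold changes of 0.91 and 0.86 (adjusted p = 0.143 and 0.0838, but 0.0295 and 0.0213 with totals and 0.0109 and 0.0203 without a filter), and let-7c-5p one of -0.15 (adjusted p = 0.810) that was above 0 with libraries scaled by totals (0.17), without chow EV library 3 (0.14) and without HFD EV library 3 (0.14).

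The endothelial list fell, with miR-126a-3p called among 4 tested members, all 4 lower adjusted over the list alone, and a median of -1.09 (camera adjusted p = 0.00653; adjusted p = 0.399 with an estimated correlation). All 4 members are arms of miR-126a or miR-126b, so the fall of this list is that of miR-126 alone. miR-126a-5p and miR-126b-3p of this list hold the same reads, and with these kept once it had too few tested members for the test. The epithelial list fell without a single call, its 13 tested members all below 0 and the median at -0.74 (camera adjusted p = 0.00142; adjusted p = 0.535 with an estimated correlation), with miR-200a-3p at -0.54, miR-200b-3p at -0.57 and miR-200c-3p at -0.65. The Dlk1-Dio3 cluster, an imprinted locus, fell with 0 of 33 tested members called, 5 members above 0 and a median of -0.45 (camera adjusted p = 0.0106; adjusted p = 0.535 with an estimated correlation). Its most abundant members in EVs were miR-379-5p at -0.20, miR-434-5p at -0.49, miR-381-3p at -0.50 and miR-411-5p at -0.27. The sign of miR-379-5p turned with libraries scaled by totals (0.069), and that of miR-411-5p without HFD EV library 3 (0.019). Without chow EV library 2 or HFD EV library 2 the call of this cluster ended (adjusted p = 0.0539 and 0.114). Of 23 lists camera called 6, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Groupings that mixed the diets reached up to 5 camera calls, so these falls are weak evidence of a diet effect as well. fry called 4, which were obesity and inflammation, immune cell, endothelial and neuron (adjusted p = 0.0335, 0.0361, 0.00677 and 0.0361).

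The red cell share of counts was 0.394 ± 0.114% in chow and 0.322 ± 0.120% in HFD EVs (exact permutation p = 0.5). The muscle share was 0.204 ± 0.15% and 0.375 ± 0.375% (exact permutation p = 0.4), a difference that turned without HFD library 3 (-0.0314 percentage points). The share of the liver list was 43.9 ± 12.0% and 24.1 ± 2.94% (exact permutation p = 0.1, the smallest possible), nearly all of it miR-148a-3p, and without that miRNA the difference turned to 0.0366 percentage points higher in HFD. The epithelial share was 2.41 ± 0.119% and 1.98 ± 0.067% (exact permutation p = 0.1). The testis X cluster share was 0.210 ± 0.257% and 0.243 ± 0.170% (exact permutation p = 0.8), a difference that turned without chow library 1 or 3 or HFD library 3 (-0.0455, -0.0374 and -0.0575 percentage points) and without miR-148a-3p (-0.0160). Of 9 tested red cell members 0 were called by edgeR over all miRNAs, and 2 were higher and 3 lower adjusted over the list alone. The 3 lower ones, miR-486a-5p (-1.35), miR-486a-3p (-1.34) and miR-486b-3p (-1.35), hold the same reads. miR-486a-5p and miR-486a-3p were called lower without a filter (adjusted p = 0.0411 and 0.0470), in the fit of all 12 libraries (0.0481 and 0.0488) and with DESeq2 (0.0282 and 0.0290). Of the others, miR-451a stood at -0.14, miR-92a-3p at -0.62, miR-144-5p at 1.8, miR-16-5p at 1.12, miR-144-3p at 0.92 and miR-363-3p at 0.61. The sign of miR-451a turned with libraries scaled by totals (0.22), without chow EV library 3 (0.16) and without HFD EV library 1 (0.26). The median of the red cell list was -0.14, and 0.78 with the same reads kept once. Medians of the other lists that camera did not call, of which fry called neuron, were -0.59 for adipogenesis, 0.17 for anti-adipogenic, -0.47 for liver, -0.21 for muscle, -0.62 for smooth muscle and fibroblast, 0.061 for the testis X cluster, 0.65 for neuron, 0.43 for neuronal activity, 0.019 for glia and -0.39 for choroid and ependyma. They were 0.49 for miR-17-92, -0.32 for miR-30, 0.070 for miR-29, -0.30 for the miR-34 and miR-449 family, -1.07 for miR-181 and 0.18 for insulin resistance, and the camera adjusted p of all of these lists lay between 0.0953 and 0.915. For miR-29 the mean was -0.016, against a median and a test direction above 0, and for insulin resistance the mean (-0.10) and the test direction were below 0. Of the adipogenesis list, miR-335-5p rose and miR-143-3p and miR-193a-3p fell, and 1 member was higher and 3 were lower adjusted over the list alone.

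In total edgeR called 17 of 389 miRNAs, 13 higher and 4 lower in HFD EVs, and each of the 17 separated the diets without overlap. At an unadjusted p under 0.05 there were 99, and 127 of 389 did not overlap, against 10% by chance. Scaling by library totals called 38, of which 33 were higher and 5 lower, and moved the median log2 fold change of all miRNAs from -0.13 to 0.16. DESeq2 called 55 and limma-voom 29. Leaving out chow library 1 or 2, or HFD library 1 or 2, gave 0 calls with edgeR, at 80, 95, 82 and 66 miRNAs with an unadjusted p under 0.05; DESeq2 then called 32, 40, 39 and 25, and limma-voom 6, 8, 2 and 2. Without chow library 3 the calls of miR-9b-5p, miR-142a-5p, miR-223-5p, miR-30a-3p, miR-193a-3p and miR-146a-5p ended (adjusted p = 0.0788, 0.0594, 0.0537, 0.0788, 0.0521 and 0.0537) and let-7g-5p and let-7i-5p were called (adjusted p = 0.0213 and 0.0379). Without HFD library 3 those of miR-223-5p, miR-30a-3p and miR-193a-3p ended (adjusted p = 0.0663, 0.06 and 0.0833). With robust fitting switched off edgeR called 15, and the calls of miR-9b-5p, miR-223-5p and miR-30a-3p ended (adjusted p = 0.0508 for each). That of miR-9b-5p also ended with limma-voom (0.0721). In the fit of all 12 libraries those of miR-193a-3p and miR-223-5p ended (0.130 and 0.138). With the replicate block, among others, those of miR-126a-3p, miR-142a-5p, miR-193a-3p, miR-223-5p and miR-9b-5p ended (0.0514, 0.0652, 0.0669, 0.111 and 0.0583).

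**Figure D1:**
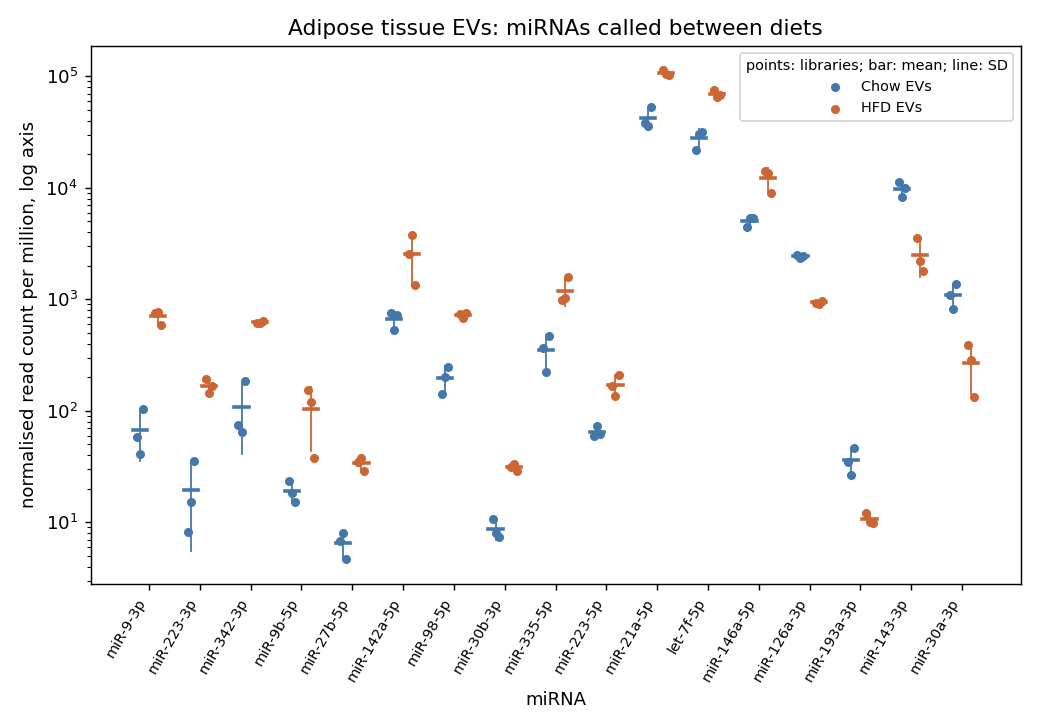
Normalised CPM (log axis) of the 17 miRNAs called between diets in adipose tissue EVs, with 3 chow and 3 HFD libraries as points, bars for means and lines for SD. miR-9-3p lies at a mean of 67.3 CPM in chow and 705 CPM in HFD, and none of the 17 overlaps between diets.

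The arms of miR-9 were followed in both sample types. In EVs miR-9-5p stood at 163 ± 85.8 CPM in chow and 654 ± 487 CPM in HFD (log2 fold change 2.01, SE 0.70, adjusted p = 0.122), which did not pass. It passed without HFD EV library 3, at a log2 fold change of 2.63. In hippocampus miR-9-3p stood at 2398 ± 909 CPM in chow and 3492 ± 172 CPM in HFD (log2 fold change 0.54, SE 0.28, adjusted p = 0.231) and passed without chow hippocampus library 3, at 0.89. Hippocampal miR-9-5p had a log2 fold change of -0.37 (SE 0.31, adjusted p = 0.433) that turned to 0.071 without that library. Per library the ratio of 5p to 3p counts was 2.39, 2.23 and 2.51 in chow EVs and 0.822, 1.51 and 0.311 in HFD EVs, against 126, 87.6 and 115.0 in chow hippocampus and 64.9, 56.9 and 51.4 in HFD hippocampus. The mouse genome holds 3 hairpins that give these arms, at chromosome 3, 88215598 to 88215686 in an intron of the lincRNA Gm3764, at chromosome 13, 83738814 to 83738885 in an exon of the lincRNA C130071C03Rik, and at chromosome 7, 79505264 to 79505353 in an intron of the lincRNA Mir9-3hg (GRCm38). Counts do not tell them apart. The call of miR-9-3p in EVs ended without chow library 1 or 2, or HFD library 1 or 2 (adjusted p = 0.0658, 0.0555, 0.0580 and 0.0841), while its log2 fold change stayed between 3.14 and 3.96 over all 6 omissions.

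**Figure D2:**
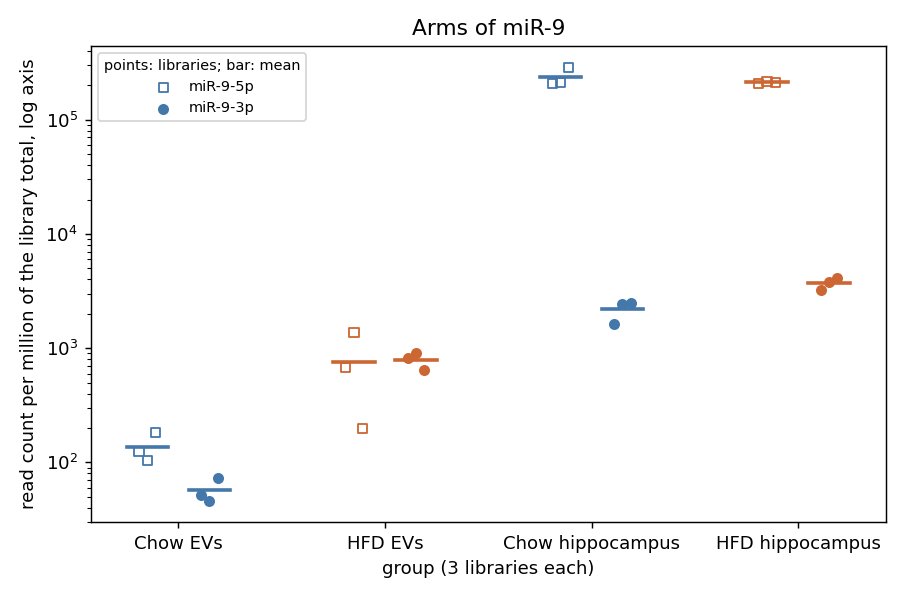
CPM of the library total (log axis) of miR-9-5p (open squares) and miR-9-3p (filled circles) in the 4 groups of 3 libraries, with bars for means. In chow EVs miR-9-3p lay between 46.3 and 72.6, and in HFD EVs between 637.6 and 908.3.

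In hippocampus, the question was which miRNAs differed with diet in the brain region. miR-22-3p, a broadly expressed miRNA, rose from 2197 ± 85.0 CPM in chow to 5095 ± 432 CPM in HFD (log2 fold change 1.21, SE 0.17, adjusted p = 0.00589), and the abundant miR-99a-5p from 13195 ± 3215 to 28488 ± 5221 CPM (1.11, SE 0.25, adjusted p = 0.0281). miR-770-5p, encoded in the imprinted Meg3 transcript, rose from 7.28 ± 2.41 to 20.5 ± 1.07 CPM (1.53, SE 0.28, adjusted p = 0.0200). The neuronal miR-129-1-3p fell from 261 ± 89.4 to 54.3 ± 5.39 CPM (-2.27, SE 0.29, adjusted p = 0.00466). The red cell miRNA miR-451a fell from 332 ± 193 to 79.9 ± 32.8 CPM (-2.05, SE 0.46, adjusted p = 0.0285), and the liver miRNA miR-122-5p from 26.2 ± 23.1 to 2.98 ± 0.45 CPM (-3.15, SE 0.62, adjusted p = 0.0235).

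Further rises were those of miR-28a-5p (log2 fold change 1.32), miR-501-3p (1.27), miR-339-5p (1.22), miR-181c-5p (1.14), miR-140-5p (1.12), miR-668-3p (1.10) and miR-543-3p (1.09). Further falls were those of miR-3470a (-4.67), miR-3470b (-4.17), miR-690 (-3.98), miR-200a-5p (-3.03) and miR-3535 (-1.93), and of miR-122b-3p, which holds the reads of miR-122-5p. For miR-6481 the HFD libraries held 1 count and the chow libraries 182, a ratio of pooled counts of 545 (95% interval 96.7 to 21656). miR-7079-3p held 1 count in chow and 227 in HFD libraries, and miR-467e-5p 73 in chow and 0 in HFD libraries, at least 72.9-fold lower over the group; both were named after their values were seen. The hairpin of miR-22 lies at chromosome 11, 75463716 to 75463810, in an exon of Mir22hg, that of miR-770 at chromosome 12, 109563692 to 109563785, that of miR-129-1 at chromosome 6, 29022619 to 29022691, in an exon of the lincRNA Gm3294, and that of miR-451a at chromosome 11, 78073170 to 78073241, between genes (GRCm38).

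**Figure D3:**
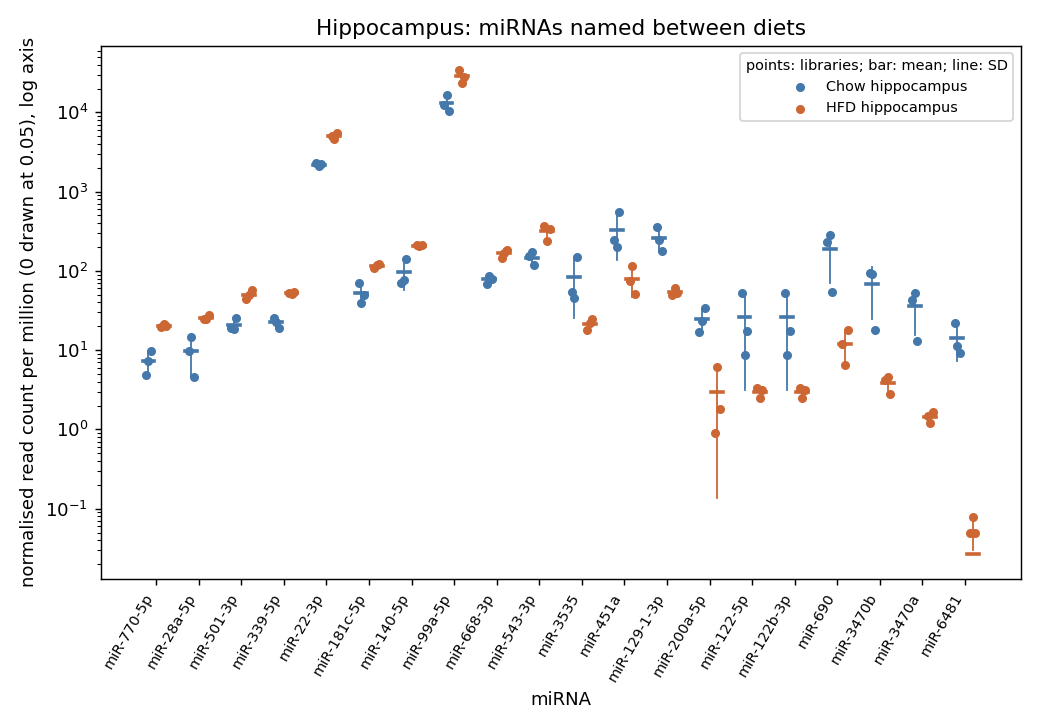
Normalised CPM (log axis, 0 drawn at 0.05) in hippocampus, with 3 chow and 3 HFD libraries as points, bars for means and lines for SD. Drawn are the 10 largest rises and the 10 largest falls among called miRNAs with at least 10 CPM in a group. miR-22-3p lies at 2197 CPM in chow and 5095 CPM in HFD, and miR-6481 at 1 count over the 3 HFD libraries.

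Of the neuron list 1 of 24 tested members rose and 5 fell, among the latter miR-129-5p (-1.05) and miR-132-3p (-0.99), the second known to follow neuronal activity; adjusted over the list alone 3 were higher and 5 lower, at a median of 0.16. Of the neuronal activity list miR-191-5p rose (1.03) and miR-132-3p and miR-146a-5p (-1.20) fell, with 1 higher and 2 lower adjusted over the list alone and a median of 0.17. Of the endothelial list miR-126a-5p rose (0.90), together with miR-126b-3p, which holds the same reads, while miR-126a-3p stood at 0.22 (adjusted p = 0.420). Of the red cell list 1 of 9 tested members fell, of the liver list miR-122-5p and miR-148a-3p (-1.40) fell among 4, and of the muscle list miR-1a-3p (-1.23) and miR-1b-5p, which holds the same reads, fell among 5. These calls ended under several settings. That of miR-132-3p ended with totals (adjusted p = 0.124), upper quartile (0.0502), the replicate block (0.0552), the fit of all 12 libraries (0.0763) and all omissions but that of chow library 3 (0.0573 to 0.201). That of miR-129-5p ended with totals (0.0545), the fit of all 12 libraries (0.0727) and the same 5 omissions (0.0543 to 0.173). That of miR-126a-5p ended with totals (0.101), the replicate block (0.0653), the same reads kept once (0.0534), the fit of all 12 libraries (0.240) and without chow library 2 or any 1 HFD library (0.0919 to 0.123). That of miR-1a-3p ended with totals (0.0745), the fit of all 12 libraries (0.455) and without chow library 1 or 2 or HFD library 1 or 3 (0.0595 to 0.173). Those of miR-191-5p and miR-148a-3p ended without chow library 2 (0.0689 for each), HFD library 1 (0.0919 and 0.0940) or HFD library 3 (0.0785 and 0.124). Shares of the red cell, muscle and liver lists were lower with HFD, at 0.0913 ± 0.0105% against 0.135 ± 0.0357% of counts for red cell, 0.0540 ± 0.0208% against 0.109 ± 0.0188% for muscle and 0.756 ± 0.171% against 1.65 ± 0.451% for liver (exact permutation p = 0.1 for each, the smallest possible). Most of the liver share was miR-148a-3p, at 16530 CPM in chow and 6262 CPM in HFD, beside 26.2 and 2.98 CPM for miR-122-5p. The share without miR-148a-3p was not computed. The epithelial share was 0.0302 ± 0.0219% against 0.0625 ± 0.0363% (exact permutation p = 0.3), and the testis X cluster share 0.000503 ± 0.000221% against 0.000480 ± 0.000337% (exact permutation p = 1).

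With camera 0 of 22 lists were called in hippocampus, 6 at an unadjusted p under 0.05, and the lowest adjusted p was 0.0729. With an estimated correlation and with fry the calls were 0 as well, at 0 and 7 lists with an unadjusted p under 0.05. The testis X cluster had 1 tested member and was not tested. By camera the count was 1 with totals, 9 without a filter and up to 3 with a library left out. Median log2 fold changes were -0.15 for adipogenesis, 0.27 for anti-adipogenic, -0.78 for obesity and inflammation, -0.76 for immune cell, -0.66 for red cell, 0.77 for endothelial, -0.77 for liver, -1.23 for muscle, 0.025 for smooth muscle and fibroblast, -0.98 for epithelial, -0.14 for glia and 0.40 for choroid and ependyma. They were 0.070 for the Dlk1-Dio3 cluster, 0.017 for let-7, 0.019 for miR-17-92, -0.49 for miR-30, -0.14 for miR-29, 0.80 for the miR-34 and miR-449 family, 0.057 for miR-181 and -0.073 for insulin resistance. The mean was below 0, against a median and test direction above 0, for neuron (-0.12), neuronal activity (-0.0098) and let-7 (-0.0090). For glia the test direction was above 0 with a mean of -0.27, and for insulin resistance both the test direction and the mean (0.058) were above 0.

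In total edgeR called 65 of 552 miRNAs in hippocampus, 24 higher and 41 lower in HFD, each without overlap between diets, and 164 had an unadjusted p under 0.05. Of all miRNAs tested, 206 did not overlap, against 10% by chance. Library totals called 33, of which 17 were higher and 16 lower, with the median log2 fold change of all miRNAs moving from -0.13 to 0.032, and upper quartile scaling called 25 higher and 28 lower. Omission of a library changed the count to 33 without chow library 1, 23 without chow 2, 123 without chow 3, 8 without HFD 1, 38 without HFD 2 and 9 without HFD 3; in the same order DESeq2 called 98, 78, 152, 71, 75 and 48. Without HFD 1 and without HFD 3 the calls of miR-770-5p, miR-99a-5p, miR-451a and miR-122-5p ended (adjusted p = 0.0671, 0.0940, 0.125 and 0.0908 without HFD 1, and 0.0739, 0.103, 0.108 and 0.0785 without HFD 3). Calls also ended without chow library 1 for miR-99a-5p and miR-451a (adjusted p = 0.0665 and 0.0542) and without chow library 2 for miR-770-5p and miR-451a (adjusted p = 0.0626 and 0.0549), whereas miR-22-3p and miR-129-1-3p were called in all 6 omissions. In the fit of all 12 libraries the calls of miR-22-3p and miR-99a-5p ended (adjusted p = 0.0570 and 0.0988), as did those of miR-28a-5p (0.164), miR-339-5p (0.143), miR-181c-5p (0.101), miR-140-5p (0.0687), miR-668-3p (0.266) and miR-543-3p (0.365). With totals those of miR-28a-5p, miR-181c-5p and miR-543-3p ended (0.0683, 0.0545 and 0.0538). They ended with upper quartile scaling for miR-140-5p and miR-3535 (0.0527 for each). The calls of all further rises named above ended without HFD 1 (0.0606 to 0.132) and without HFD 3 (0.0739 to 0.153). That of miR-28a-5p also ended with robust fitting switched off (0.0511), the same reads kept once (0.0526) and thinning (0.0664). Without a filter that of miR-690 ended (0.0559). The call of miR-200a-5p ended in all omissions but that of HFD 2 (0.0510 to 0.108), and that of miR-3535 in all but that of chow 3 (0.0537 to 0.148). Without HFD 1 those of miR-3470b and miR-690 ended (0.0606 and 0.0671). With the replicate block those of miR-99a-5p, miR-140-5p and miR-690 ended (0.0540 for each), as did those of miR-28a-5p, miR-181c-5p and miR-543-3p (0.0560 for each).

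Whether diet moved the same miRNAs in EVs and hippocampus was tested over the 335 miRNAs tested in both, of which 15 were called in EVs and 47 in hippocampus. Of these, 3 were called in both by edgeR, where 2.10 would be for independent lists (exact hypergeometric p = 0.353), and 1 of them, miR-30a-3p, fell in both (-2.02 in EVs and -0.85 in hippocampus), where 0.904 in the same direction would be. miR-146a-5p rose in EVs (1.28) and fell in hippocampus (-1.20), and miR-30b-3p likewise (1.84 and -0.92). The count in the same direction was 8 with DESeq2, 5 with limma-voom, 4 without a filter and 0 with the replicate block. An expected count was computed for the comparison as designed alone. The hippocampal call of miR-30a-3p ended with median-of-ratios, totals and upper quartile scaling (adjusted p = 0.0627, 0.171 and 0.0654), without a filter (0.116), in the fit of all 12 libraries (0.183), with the replicate block (0.0674) and in all omissions but that of chow library 3 (0.0919 to 0.277). Its EV call ended with robust fitting switched off (0.0508), with the replicate block (0.0602) and in all 6 omissions (0.06 to 0.169). In hippocampus the call of miR-30b-3p ended with totals (0.110), upper quartile (0.0658), no filter (0.158), the fit of all 12 libraries (0.0980), the replicate block (0.0929), thinning (0.0516) and the same 5 omissions (0.0537 to 0.239). That of miR-146a-5p ended there with totals (0.06), with the replicate block (0.0504) and without chow library 1 or HFD library 1, 2 or 3 (0.0537, 0.0919, 0.0721 and 0.138). The EV calls of miR-30b-3p and miR-146a-5p ended with the replicate block (0.06 for each). The former also ended without chow library 1 or 2 or HFD library 1 or 2 (0.0658, 0.0654, 0.0907 and 0.131). The latter ended without chow library 1, 2 or 3 or HFD library 1 or 2 (0.117, 0.0758, 0.0537, 0.130 and 0.169). Across miRNAs, which are not independent replicates, the fold changes had a Pearson r of 0.0123 (permutation p = 0.822) and a Spearman rho of 0.0303 (permutation p = 0.580).

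The difference of the diet effects was tested in a fit of all 12 libraries. No list was tested on it. Among the 10 miRNAs with the smallest p, the log2 diet fold in EVs minus that in hippocampus was 5.81 for miR-223-3p (SE 0.997, adjusted p = 0.00242), 3.15 for miR-342-3p (SE 0.55, adjusted p = 0.00242), 3.03 for miR-142a-5p (SE 0.56, adjusted p = 0.00380), 2.54 for miR-146a-5p (SE 0.37, adjusted p = 0.00108) and 1.8 for miR-21a-5p (SE 0.37, adjusted p = 0.00735). For miR-9-3p it was 2.92 (SE 0.48), for miR-30b-3p 2.87 (SE 0.49), for miR-335-5p 2.59 (SE 0.48) and for miR-3470a 4.75 (SE 0.81). Hippocampal miR-223-3p lay near the floor, at 6.39 ± 6.04 CPM in chow and 0.97 ± 0.27 CPM in HFD. Its hippocampal log2 fold change of -2.72 was not called (edgeR adjusted p = 0.0874). Those of miR-342-3p, miR-142a-5p, miR-21a-5p, miR-9-3p and miR-335-5p were not called there either (0.132 to 0.345). miR-467e-5p had the smallest adjusted p, 3.89e-05, with 0 counts in HFD hippocampus and 18.1 ± 6.78 CPM in HFD EVs against 9.58 ± 2.51 CPM in chow EVs. The hippocampal side of each difference cannot be told apart from depth and column heading, which went together with diet there. In total 30 of 519 differed, 25 with the higher diet fold in EVs and 5 with the lower, and 117 had an unadjusted p under 0.05. Median-of-ratios scaling called 46, at 23 each way, upper quartile scaling 25 and 11, and without HFD EV library 2 the count was 15. The call of miR-21a-5p ended without chow EV library 1 or 2, HFD EV library 2 or chow hippocampus library 3 (adjusted p = 0.0667, 0.0636, 0.0730 and 0.0713), and that of miR-142a-5p without HFD EV library 2 (adjusted p = 0.05).

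**Figure D4:**
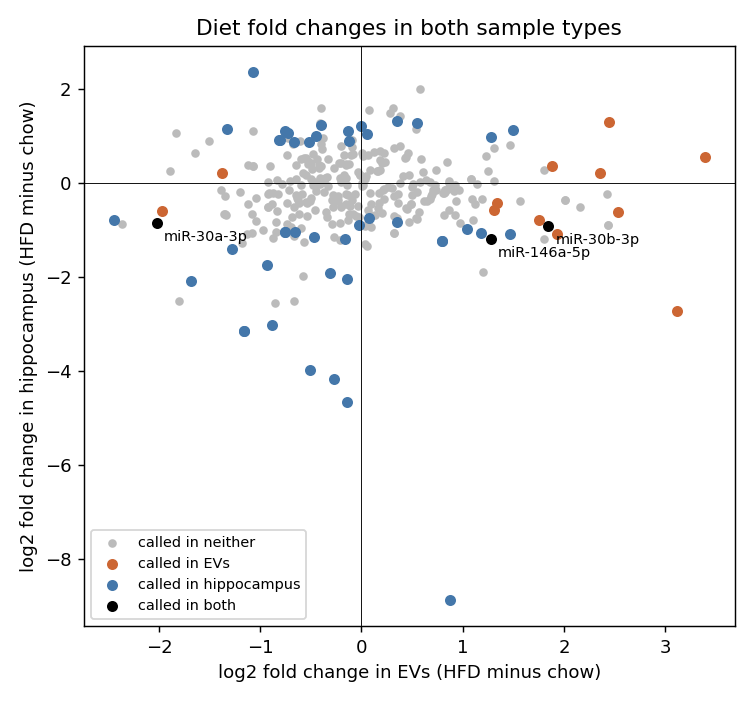
Log2 fold changes (HFD minus chow) in EVs on the horizontal axis and in hippocampus on the vertical axis, with a point for each of the 335 miRNAs tested in both and colours for calls. The Pearson r was 0.0123, and the lowest point is miR-467e-5p, at 0 counts in HFD hippocampus, where the fitted fold change is no bound.

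What each sample type held was described in chow mice. No list was tested for this contrast. Of the miRNAs higher in EVs, miR-141-3p stood at 1505 ± 181 CPM in EVs and 0.461 ± 0.621 CPM in hippocampus, miR-200c-3p at 3893 ± 659 and 4.26 ± 3.10 CPM, miR-10b-5p, encoded among Hox genes, at 120691 ± 19822 and 40.2 ± 21.8 CPM, miR-10a-5p at 87749 ± 13065 and 77.5 ± 48.1 CPM, and miR-215-5p at 7022 ± 10679 and 1.69 ± 0.225 CPM. With 1 to 3 counts in hippocampus, the ratios of pooled counts were 3107 (95% interval 557 to 122773) for miR-10b-3p, 2063 (570.4 to 17044) for miR-10a-3p, 2457 (440.2 to 97120) for miR-465c-5p, 1314 (363 to 10857) for miR-465b-5p and 860.5 (294 to 4178) for miR-615-3p. Higher in hippocampus were the neuronal miR-124-3p, with 3 counts in EVs and a ratio of 10200.1 (3490.1 to 49463), miR-137-3p (ratio 1859, interval 333 to 73446), miR-384-5p (559, interval 155 to 4618) and miR-488-3p (499 ± 86.0 and 1.02 ± 1.08 CPM). The oligodendrocyte miR-219a-2-3p, with 0 counts in EVs, was at least 2091-fold higher, miR-873a-5p at least 863-fold and miR-219b-5p at least 310.3-fold. The choroid plexus miRNA miR-1298-5p had a ratio of 3930.0 (1088 to 32454), and miR-9-5p stood at 226683 ± 39018 CPM in hippocampus and 177 ± 89.2 CPM in EVs. edgeR called 412 of 519 miRNAs, 179 higher in EVs and 233 higher in hippocampus, with 415 at an unadjusted p under 0.05. Scaling by totals moved the median log2 difference from -0.52 to -0.83.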

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

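Tests chosen only after the result was seen were those of brain RNA and of scaling for miR-9-3p, of blood and of a factor shared by all miRNAs for the leukocyte miRNAs, and both tests of the hippocampal miRNAs present with 1 diet alone. The tests by thinning and by leaving out miR-148a-3p rest on settings that were also chosen after seeing the data.

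A test of the difference itself called 30 miRNAs, for which the HFD minus chow change differed between EVs and hippocampus. The log2 diet fold in EVs minus that in hippocampus was 2.54 for miR-146a-5p, 2.92 for miR-9-3p, 2.87 for miR-30b-3p, 4.75 for miR-3470a, 3.15 for miR-342-3p, 5.81 for miR-223-3p, 3.03 for miR-142a-5p, 2.59 for miR-335-5p and 1.8 for miR-21a-5p, and miR-467e-5p had an adjusted p of the difference of 3.89e-05. For miR-223-3p the difference rests partly on hippocampal levels near the floor (6.39 ± 6.04 CPM in chow and 0.97 ± 0.27 CPM in HFD). For miR-467e-5p and miR-3470a it rests mainly on hippocampus, since their EV log2 fold changes were 0.87 and -0.14 and not called. In hippocampus depth and column heading went together with diet, so the test cannot tell a difference of diet effects from these. Of 100 drawn regroupings, the real one included, 2 gave at least 30 calls. The other gave 39 and is the real grouping with the hippocampus diets exchanged, which turns the difference of the diet effects into their sum. Every further regrouping mixed the diets in EVs, in hippocampus or in both, which weakens the diet effect of each sample type that was mixed. The draw bears on whether the diet labels matter at all, not on whether their effects differ between sample types.

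The rise of miR-9-3p in HFD EVs stood beside a smaller change of miR-9-5p. Brain RNA carried into the HFD EV libraries argues for a ratio of 5p to 3p counts like that of hippocampus, and the highest ratio in HFD EVs was 1.51 against a lowest hippocampal ratio of 51.4. With libraries scaled by their totals the adjusted p of miR-9-3p was 0.00219 (range 5.61e-15 to 0.0294 over the alternatives that kept all 6 libraries). Totals moved the median log2 fold change of all EV miRNAs from -0.13 to 0.16, so that setting could only strengthen a rise. The move is small beside the log2 fold change of 3.39, which argues against the choice of scaling as the whole cause. A change of the vesicles or of their cells of origin with diet is a hypothesis that may account for the rise and was not tested. No other miRNA matched the counts of miR-9-3p within 5% in EVs, and its adjusted p was 0.00863 with the same reads kept once; mispriming and partial sharing of reads with miR-9b were not tested.

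The leukocyte miRNAs that rose in HFD EVs may reflect more leukocyte RNA in or on the vesicles with HFD, a biological difference by design that was not tested. The lower share of miR-148a-3p in HFD EVs raises all other miRNAs by 1 factor and is argued against as the whole cause by the epithelial list, whose upper quartile of log2 fold changes was -0.57 against a lower quartile of 0.62 for the leukocyte list. The adjusted p of the latter without miR-148a-3p, 7.25e-04 against 6.28e-04 with it, could not have moved with such a factor. Blood in the HFD preparations stays open, since the red cell list held miR-486a-5p at -1.35 (called lower with DESeq2, without a filter and in the fit of 12 libraries), which goes against it, and miR-144-5p at 1.8 (not called), and its median of -0.14 became 0.78, with an upper quartile of 1.18, with the same reads kept once, which overlaps the leukocyte list (lower quartile 0.79, median 1.54). The call rests on the preset correlation, since the adjusted p was 0.399 with an estimated one.

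In hippocampus the HFD libraries were deeper than the chow libraries. The number of counts by itself as the whole cause of the 65 calls is argued against by thinning. With all 6 libraries thinned to 2331091 counts, at least 53 of the 65 were still called in each of 10 draws. Of the called miRNAs, 21 of 24 higher and 36 of 41 lower reached 10 CPM in a group, so thinning was a mild test. It cannot remove anything else that went together with the deeper HFD libraries. For 3 miRNAs (miR-467e-5p, miR-6481 and miR-7079-3p) all libraries of 1 diet held at most 3 counts while all of the other held at least 3 CPM, where no other split of the 6 libraries gave any; in EVs the real split gave 0 and other splits up to 2. Carry-over of blood, muscle or liver RNA into the chow libraries stays open, since 0 of only 3 miRNAs standing on lists of 10, 9 and 6 decides nothing and the shares of these lists were higher in chow (0.135 against 0.0913%, 0.109 against 0.0540% and 1.65 against 0.756%). Most of the liver share was miR-148a-3p (16530 CPM in chow and 6262 CPM in HFD), so that share rests largely on 1 miRNA. Separate counting of HFD and chow libraries might give such a pattern and cannot be told apart from diet, since diet, depth and column heading went together and 5 further entries are blank for the HFD libraries alone.

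Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 17 calls in EVs and the highest other 4, 65 in hippocampus and the highest other 0, and 412 between sample types and the highest other 0; in each case 1 split of 10 reached the real value. For lists the real split called 6 in EVs and the highest other 5, and 0 in hippocampus, which all 10 splits reached, and the highest other 4. Of 100 drawn regroupings 2 gave at least 1 miRNA called in both with the same direction, the other being the grouping with exchanged diets at 2. That count was fixed by the few calls in other splits and says nothing about a shared direction, and independent lists would give 0.904. A correlation of fold changes as far from 0 as 0.0123 came from 95 of 100 regroupings, the highest other being 0.356, and chance cannot be excluded there.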

How the results depend on the processing

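Alternatives that kept miRNAs with the same reads once, thinned the libraries or left out miR-148a-3p were chosen after seeing the data. Calls in EVs, 17 in the comparison as designed, numbered 29 with median-of-ratios size factors, 38 with library totals, 28 with upper quartile scaling, 56 without a filter, 27 at a mean of at least 10 CPM, 55 with DESeq2, 29 with limma-voom, 31 with the same reads once, 38 with all 12 libraries in 1 fit and 15 with robust fitting switched off; all 17 were among those of the scalings, filters and DESeq2, 16 among those of limma-voom (without miR-9b-5p), 14 with robust fitting off (without miR-9b-5p, miR-223-5p and miR-30a-3p) and 15 among those of the 12-library fit. In hippocampus, 65 became 33 with totals (31 shared), 109 with DESeq2 (all 65 shared) and 29 with all 12 libraries in 1 fit (23 shared). The difference between sample types, 30, became 46 with median-of-ratios size factors and 76 with DESeq2. miR-9-5p in EVs passed without a filter (2.24), with DESeq2 (2.05) and in the fit of 12 libraries (2.07), and miR-148a-3p in EVs without a filter (-1.05) and with DESeq2 (-1.23). miR-486a-5p in EVs was called lower without a filter (-1.16), with DESeq2 (-1.33) and in the fit of 12 libraries (-1.31), and miR-146b-5p higher with totals (1.30) and without a filter (1.16). Signs turned for miR-451a in EVs (0.22 with totals, 0.065 without a filter, 0.021 at 10 CPM, 0.038 with the same reads once), miR-379-5p in EVs (0.069 with totals) and let-7c-5p in EVs (0.17 with totals, 0.062 without a filter), none of which was called. The count of miRNAs called in both with the same direction, 1, became 2 with median-of-ratios size factors, 2 with totals, 4 without a filter, 3 at 10 CPM, 8 with DESeq2, 5 with limma-voom and 18 at an unadjusted p under 0.05, and the correlation of folds became -0.0080 without a filter. Lists called in EVs, 6, became 0 with an estimated correlation (2 at an unadjusted p under 0.05), and those in hippocampus, 0, became 1 with totals and 9 without a filter. Without the most abundant miRNA the liver share in EVs differed by 0.0366 and the testis X cluster share in EVs by -0.0160 percentage points. Apart from filters, which change the miRNAs tested, and the estimated correlation, which widens the null, the cause was not tested. With each library left out in turn, calls ranged from 0 to 21 in EVs, 8 to 123 in hippocampus and 15 to 42 for the difference between sample types, those in both with the same direction from 0 to 3, the correlation of folds from -0.060 to 0.093 and lists in hippocampus from 0 to 3; an omission also leaves fewer samples. The log2 fold change ranged from 3.14 to 3.96 for miR-9-3p in EVs, 1.34 to 2.65 for miR-9-5p in EVs, 0.31 to 0.89 for miR-9-3p in hippocampus, -0.53 to 0.071 for miR-9-5p and for miR-9b-3p in hippocampus, -0.40 to 1.07 for miR-155-5p in EVs, -0.44 to 0.26 for miR-451a in EVs, -0.53 to 0.019 for miR-411-5p in EVs and -0.37 to 0.14 for let-7c-5p in EVs. HFD minus chow shares ranged from -0.0314 to 0.340 for muscle and -0.0575 to 0.181 for the testis X cluster in EVs and from -1.31e-04 to 2.03e-04 for the latter in hippocampus. The replicate number as a block gave 9 calls in EVs, 35 in hippocampus, 0 in both with the same direction, 27 for the difference between sample types (34 with diet and number as an animal) and 401 between sample types. Deviations of samples with the same number correlated between -0.45 and 0.25, and not every sample correlated best with its own number. Whether the numbers pair the samples cannot be told from this, since paired samples need not share deviations. Of single miRNAs under the other settings, EVs kept direction and side of the threshold in 496 results, with 25 newly past it and 14 no longer past it; hippocampus kept 365 with 62 no longer past it, and all 110 of the difference and 199 between sample types were kept. Known miRNAs alone were run for EVs, since the other comparisons tested no predicted ones, and a pseudocount was not varied since the values are counts. Depth sets floors of 0.505 to 1.64 CPM in EVs and 0.233 to 1.29 CPM in hippocampus.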

Other observations

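Both tests of arm ratios were planned before the result was seen; the values per library were looked at after.

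Some miRNAs varied within the EV groups. miR-215-5p stood at 18091, 644.5 and 906 CPM in chow EV libraries 1, 2 and 3 and at 959, 10277 and 13363 CPM in the HFD libraries (adjusted p = 0.924), and miR-194-5p at 3235, 249.7 and 332 CPM and at 279, 1992 and 2324 CPM (adjusted p = 0.924). The muscle miRNA miR-1a-3p stood at 1309.9, 1175 and 207 CPM in chow and at 146, 1181 and 3339.9 CPM in HFD EV libraries (adjusted p = 0.710). miR-465c-5p of the testis X cluster stood at 67.2, 418 and 104 CPM in chow and at 71.2, 124 and 286 CPM in HFD EV libraries (adjusted p = 0.881).

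That the 2 arms of a hairpin move apart with diet was tested as a hypothesis with limma on the log2 ratio of 5p to 3p counts. In EVs 2 of 105 hairpins differed, miR-362 by 2.76 (SE 0.34, adjusted p = 0.00703) and miR-98 by 1.88 (SE 0.34, adjusted p = 0.0424), and 20 had an unadjusted p under 0.05. In hippocampus 15 of 157 differed and 39 had an unadjusted p under 0.05. Of the 15 ratios 10 were higher and 5 lower with HFD. The ratio was lower for miR-200a (-2.41, adjusted p = 0.0168), miR-423 (-1.56, adjusted p = 0.0180), miR-27a (-1.99, adjusted p = 0.0341) and miR-9 (-0.91, adjusted p = 0.0341), and higher for miR-140 (1.65, adjusted p = 0.0180) and for miR-98 (1.78, adjusted p = 0.0378), the latter as in EVs. For miR-9 in EVs the difference was -1.70 (SE 0.56, adjusted p = 0.231), in the same direction as in hippocampus but not past the threshold. A change of arm choice with diet may underlie these 2 and 15 differences, as may a change in the recovery of short RNA between libraries, which was not tested. The hairpins named were chosen after their values were seen.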
